A study of Homo sapiens with 12 samples.

How the data were processed

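Transcript levels were measured by RNA sequencing in MV4-11 and THP-1, human acute myeloid leukaemia cell lines that carry MLL gene fusions. Cells of each line received a control short hairpin RNA (shControl) or a short hairpin RNA against CYTH4 (shCYTH4). Each of the 4 groups held 3 libraries, 12 in all, and every library belonged to 1 group. Per the labels, poly(A) RNA was made into strand-marked libraries by the dUTP method and read from both ends at 150 bases on a NovaSeq instrument. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which can be technical.

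The deposited table lists 34626 genes with 24 columns of values, of which 0 lacked a sample. Per the file headers, 12 columns hold a deposited estimated count per gene and library, in whole numbers that were not normalized. Low values pile up at multiples of 4, so 1 count is not 1 fragment. Whether the counting used the strand is not stated, so levels of named genes that overlap a gene with a mean FPKM of at least 1 are uncertain. These are C3, IL4I1, BCL2L2-PABPN1, ASH1L-AS1, MT-ND4 and MT-ATP6 on the same strand, and FLRT1, P4HA2, CTSW, MS4A4E, FDPS and ALG5 on the other. The other 12 columns hold FPKM per the file headers, a number of fragments scaled to transcript length and to library depth, as the authors deposited them. The denominator of the FPKM is not stated. Per the submitters' processing notes, fastp, StringTie and edgeR were used, without a version, role or order for any of them. The aligner, the genome build and the annotation release are not given in the sources used here. Column names carry the short forms SC and Sh, which were read as shControl and shCYTH4; the labels do not spell them out. Positions are those of the file. Of the 34626 identifiers, 32815 are in GENCODE release 29 for GRCh38, 32809 of these overlap the position given there, and 17778 have the same start and end.

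Depth was 71730093 to 77782719 estimated counts per library, and 12 counts, the floor used for a group at 0, made up a CPM of 0.154 to 0.167. That floor is 3 fragments if 4 counts stand for 1. Intervals and floors cover counting error or the spread between these libraries only. TMM factors ran from 0.916 to 1.08. Genes with an FPKM of at least 1 in at least 3 libraries, 12350 in number, were tested with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood, TMM scaling, robust moderation). The model had 4 group means and 8 residual degrees of freedom. The test planned for FPKM was limma on log2(FPKM + 1), with edgeR to be used if the table also held raw counts. The table held whole-number estimated counts rather than raw counts. They were tested with edgeR, a departure from the wording of the plan, and limma on log2(FPKM + 1) was run as an alternative. Counts divided by 4 were a further added alternative.

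The contrasts were shCYTH4 against shControl in each line, the difference between those responses (MV4-11 response minus THP-1 response), and MV4-11 against THP-1 in the control libraries. Adjusted p-values are Benjamini-Hochberg values over the genes tested, a gene was called at an adjusted p under 0.05, and a change of at least 1 on the log2 scale was counted as well. The overlap of the calls of the lines was tested with Fisher's exact test, two-sided. Exact permutation tests, two-sided, were used for single values per library; with 3 libraries against 3, the smallest p they allow is 0.1. Group values are given as mean ± SD with n = 3, and SE is the standard error of a fitted log2 change.

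The groups, comparisons, tests, alternatives, gene lists and the rule for named genes were set before the data were examined. That plan named edgeR for raw counts only. Per line, the rule named CYTH4, the 8 called genes with the largest rise and the 8 with the largest fall, and up to 3 called members of each of the 6 lists with the smallest p. The rises and falls had to have a gene symbol, a mean FPKM of at least 2 in the higher group and no overlap between the 3 libraries of each arm. Up to 6 genes per direction were named among those called in both lines, 4 per direction for the difference between the lines and 5 per direction for the control libraries. Other genes are said to be chosen after their values were seen. The 32 lists of pathways, organelles and cell types hold 625 genes, of which 607 were found and 18 were not; 27 lists had at least 5 tested members and were tested. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the 27 lists. An estimated correlation and fry, which asks whether members move one way on balance without comparing them with other genes, were run beside it. CYTH4 was left out of the test of its own list. Gene ontology terms were tested with Fisher's exact test, one-sided, after the calls were seen, among tested genes with an ontology entry in the file.

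The same code was tested on simulated data with the same depths and the fitted spread of each gene. Apart from planted changes, a gene had the same mean level in all libraries and lines, and no library stood apart. Recovery and false calls can therefore differ in the real libraries. There were 200 planted changes per comparison of 1 line and 8 false calls in either line. In MV4-11, 20.9% of planted 1.5-fold, 67.2% of planted 2-fold and 93.9% of planted 4-fold changes were recovered. For THP-1 these shares were 17.9%, 64.2% and 97.0%. For the difference between the lines they were 12.7%, 33.6% and 89.4%, with 13 false calls.

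Alternatives, changed one at a time, covered the pseudocount (0.1), the filter (none beyond a value above 0 in 3 libraries, or a mean FPKM of at least 5), the scaling and an adjusted p under 0.01. The scalings were centring on the median, quantile normalization and totals without mitochondrially encoded genes. Further ones were the libraries of 1 line alone, array weights, plain moderation, a replicate block, DESeq2 1.42.0 and its size factors, and each library left out in turn. Added as alternatives after seeing the data were the limma test, planned for a table without raw counts, and the divided counts. A filter on the higher group of each comparison was added then too. So was a test without genes whose level in a line stays under 3% of that in the other line. The fit without THP-1 shCYTH4 replicate 3 was also added for the comparisons that do not use that library. Figures were drawn with matplotlib 3.10.9. Reads were not had, so alignment and quantification were not analysed here.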

Results

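The data are 12 libraries of poly(A) RNA from MV4-11 and THP-1, leukaemia cell lines with monocytic features. Each line gave 3 libraries labelled shControl and 3 labelled shCYTH4. The question was what silencing CYTH4 does to the transcripts of these cells. CYTH4 encodes cytohesin 4, a guanine nucleotide exchange factor for ARF GTPases found mainly in blood cells. Total estimated counts ran from 71730093 in THP-1 shCYTH4 replicate 1 to 77782719 in MV4-11 control replicate 3. Between 10251 and 11703 genes per library had an FPKM of at least 1. The monocyte marker LYZ, lysozyme, reached a group mean of 1707 FPKM, while T cell markers reached at most 1.31 FPKM, epithelial and fibroblast markers 2.94, megakaryocyte markers 1.17, erythroid markers 6.19 and B cell markers 9.96.

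CYTH4 (ENSG00000100055, chromosome 22, 37282027 to 37315341) fell in THP-1 and showed no measurable change in MV4-11. In THP-1 it went from 26.3 ± 5.64 FPKM in the controls to 15.4 ± 0.366 FPKM with shCYTH4 (n = 3 each), 54.0% of the control level by edgeR (95% interval 41.0% to 71.2%). The log2 change was -0.89 (SE 0.19, adjusted p = 0.0338). In MV4-11 the level was 18.3 ± 2.44 FPKM in the controls and 19.5 ± 3.58 FPKM in the libraries labelled shCYTH4 (n = 3 each), 101% of the control level (95% interval 76.5% to 132%). The log2 change there was 0.01 (SE 0.19, adjusted p = 0.988), so the MV4-11 comparison is between libraries that differ in their label and not in measured CYTH4. The difference between the responses was 0.90 on the log2 scale (SE 0.26) and did not pass the test over all tested genes (adjusted p = 0.126). For CYTH4 taken alone, without adjustment for the other genes, the 95% interval of this difference was 0.34 to 1.46, all of it positive. In the control libraries CYTH4 was lower in MV4-11 than in THP-1 (log2 -0.50, SE 0.19, adjusted p = 0.0332). The THP-1 call was lost without control replicate 1 (log2 -0.93, adjusted p = 0.0539), control replicate 2 (-0.67, 0.147), shCYTH4 replicate 1 (-0.89, 0.145) or shCYTH4 replicate 2 (-0.87, 0.126).

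**Figure D1:**
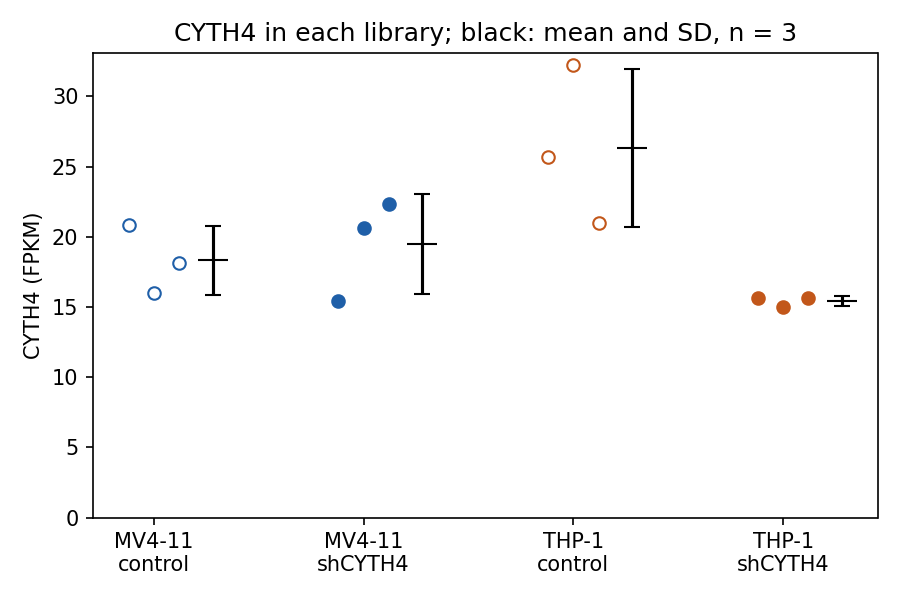
CYTH4 in FPKM in each of the 12 libraries, with the mean and SD of each group of 3. The 3 THP-1 shCYTH4 libraries lie between 15.0 and 15.7 FPKM, below all 3 THP-1 controls, which reach 32.2, while both MV4-11 groups overlap at 15.5 to 22.3.

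In MV4-11, the largest falls under the naming rule in the libraries labelled shCYTH4 were those of CXCL10, CXCL14 and C3. CXCL10 (ENSG00000169245, chromosome 4, 76021118 to 76023497), an interferon-induced chemokine, was at 2.95 ± 1.92 FPKM in the controls and at 0 in all 3 libraries labelled shCYTH4, at least 22.6-fold lower at a floor of 12 counts per library (adjusted p = 0.00353). CXCL14 (ENSG00000145824), another chemokine, fell from 8.37 ± 0.897 to 0.237 ± 0.0768 FPKM (n = 3 each), a log2 change of -5.21 (SE 0.44). Complement C3 (ENSG00000125730), whose interval overlaps that of GPR108 on the same strand, fell from 4.71 ± 0.452 to 0.242 ± 0.0235 FPKM (log2 -4.33, SE 0.34). IL4I1 (ENSG00000104951), a secreted amino acid oxidase that overlaps NUP62, fell from 28.1 ± 13.8 to 2.93 ± 0.143 FPKM (log2 -3.34, SE 0.31). Falls were also seen for EBI3, a subunit of the cytokines IL-27 and IL-35 (log2 -3.15, SE 0.64), the stress-inducible IER3 (-2.31, SE 0.37), the sulfotransferase CHST2 (-2.20, SE 0.20) and RTL8C (-2.20, SE 0.24). Adjusted p-values of these 8 falls ran from 3.43e-05 to 0.0274.

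Under the naming rule, the largest rise in MV4-11 was that of TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559), a pseudokinase induced by the integrated stress response. It went from 4.78 ± 1.27 to 29.1 ± 2.06 FPKM (log2 2.52, SE 0.45, adjusted p = 0.0297). This call, like that of PCK2, was lost when any 1 of the 6 MV4-11 libraries was left out. By edgeR, TRIB3 kept its call in the MV4-11 libraries alone (adjusted p = 3.21e-04) and without THP-1 shCYTH4 replicate 3 (adjusted p = 1.55e-05). The mitochondrial PEP carboxykinase PCK2 rose from 8.17 ± 2.05 to 38.5 ± 1.38 FPKM (log2 2.15, SE 0.42), and CBS, cystathionine beta-synthase, from 1.34 ± 0.531 to 4.88 ± 1.41 FPKM (log2 1.78, SE 0.37). NIBAN1, known as a stress-induced gene, rose by a log2 change of 2.02 (SE 0.30) and G0S2, an inhibitor of lipolysis, by 2.31 (SE 0.52). The G0S2 call was lost under 13 of 19 alternatives, while NIBAN1 kept its call under all 20. FLRT1 rose by 1.99 (SE 0.40), APOL6 by 1.99 (SE 0.39) and the interferon-induced XAF1 by 1.70 (SE 0.33). Adjusted p-values of the 8 rises ran from 0.00454 to 0.0488. All 3 libraries labelled shCYTH4 lay above all 3 controls for each, as the naming rule required.

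**Figure D2:**
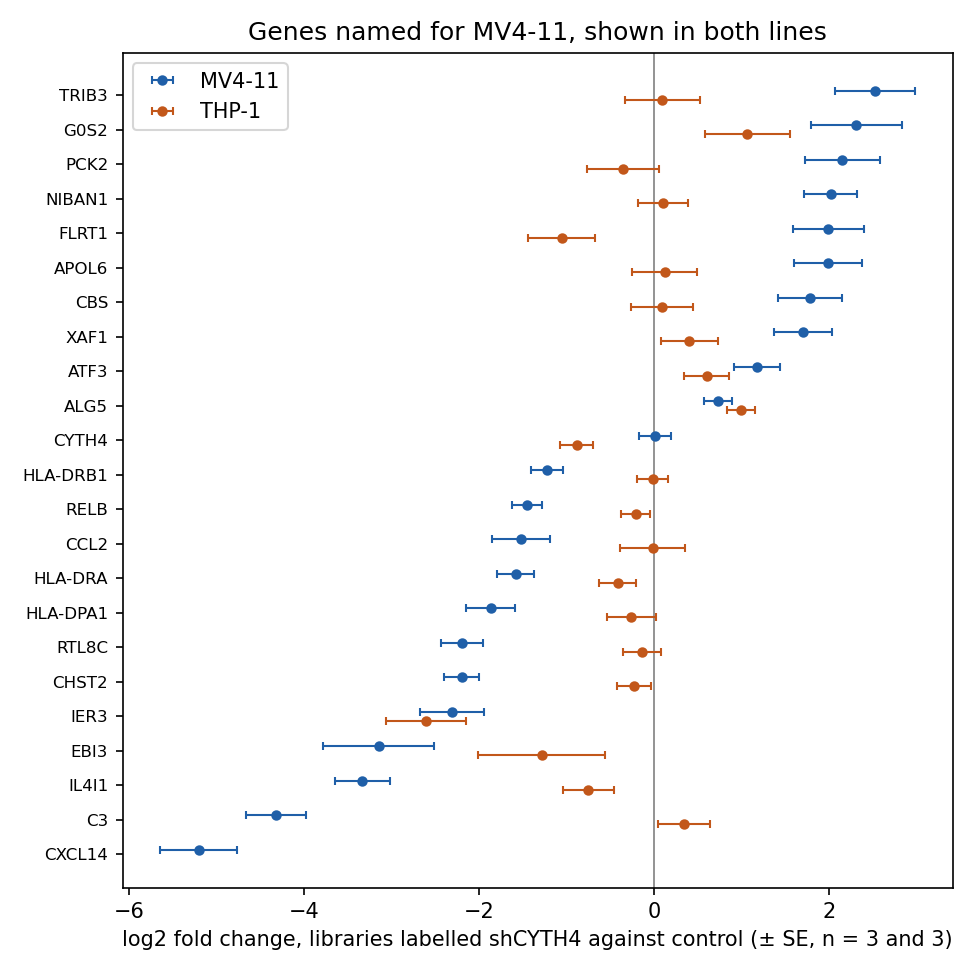
Log2 change of the named genes in MV4-11, with bars for the standard error (3 libraries per arm); CXCL10, at 0 in 1 arm, is given as a bound in the text. The other values run from -5.21 for CXCL14 to 2.52 for TRIB3.

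As groups, inflammatory and antigen presentation genes fell in MV4-11. All 15 tested members of the NF-kB and inflammatory list were below 0, with a median log2 change of -0.95 (camera adjusted p = 1.6e-19, and adjusted p = 0.0262 with an estimated correlation). Of these, 6 were called lower over all genes and 14 adjusted over the list alone. RELB, an NF-kB subunit, fell from 9.17 ± 1.80 to 3.52 ± 0.297 FPKM (log2 -1.45, SE 0.17) and the chemokine CCL2 from 3.73 ± 1.00 to 1.36 ± 0.209 FPKM (log2 -1.53, SE 0.33). All 7 tested MHC class II genes were below 0, with a median of -1.19, or -0.77 in limma on log2(FPKM + 1) (camera adjusted p = 1.19e-17, and adjusted p = 0.0295 with an estimated correlation); 4 were called lower and 7 adjusted over the list alone. HLA-DRA fell from 49.8 ± 15.8 to 17.5 ± 2.03 FPKM (log2 -1.58, SE 0.21), with falls of HLA-DPA1 (log2 -1.87, SE 0.28) and HLA-DRB1 (-1.22, SE 0.18) beside it. Fry also called these lists, and no other list, in this line. With an estimated correlation both calls were lost without shCYTH4 replicate 1 (adjusted p = 0.0682 for the inflammatory and 0.0708 for the MHC class II list), 2 (0.0548 for both) or 3 (0.0760 for both). The MHC class II call was also lost without THP-1 control replicate 1 (0.0532) or THP-1 shCYTH4 replicate 1 (0.0561).

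The list of the unfolded protein and integrated stress response had a median log2 change of 0.54 in MV4-11, with 16 of 21 members above 0 (camera adjusted p = 1.69e-05, but adjusted p = 0.223 with an estimated correlation). The 5 members below 0 code for chaperones and other folding factors of the endoplasmic reticulum: HSPA5 (-0.13), SDF2L1 (-0.94), PDIA4 (-0.34), HSP90B1 (-0.18) and CALR (-0.62), so the rise was not one of the whole list. TRIB3 and ATF3 were called higher over all genes, and 10 members were higher and 2 lower adjusted over the list alone. ATF3, a stress-induced transcription factor, rose from 0.600 ± 0.151 to 1.43 ± 0.244 FPKM (log2 1.18, SE 0.26). A further 7 lists passed with the preset correlation, none of them with an estimated correlation (adjusted p = 0.550 to 0.578). Mitochondrially encoded mRNAs (median -0.30, 13 of 13 below 0), heat shock genes (-0.30, 13 of 13 below 0), MYC and ribosome biogenesis genes (-0.21, 14 of 20) and mitosis genes (-0.13, 16 of 20) were lower. Cholesterol synthesis genes (0.20, 16 of 19 above 0), S phase and DNA replication genes (0.16, 18 of 23) and interferon-stimulated genes (0.24, 14 of 23) were higher. Under quantile normalization the medians of the mitochondrially encoded and the interferon-stimulated list were -0.07 and 0.03, and in limma on log2(FPKM + 1) those of the heat shock, MYC and mitosis lists were -0.19, -0.12 and -0.04. Over all genes, CDC20 was the 1 mitosis gene called lower and XAF1 the 1 interferon-stimulated gene called higher; the other 5 lists had 0 called members, and adjusted over the list alone 0 to 5 members of the 7 lists passed by edgeR. The interferon-stimulated call was lost without control replicate 1 (adjusted p = 0.114), shCYTH4 replicate 1 (0.0667), 2 (0.0615) or 3 (0.0607), or THP-1 shCYTH4 replicate 3 (0.0727). The mitosis call was lost without control replicate 3 (0.0857) or shCYTH4 replicate 2 (0.0641) or 3 (0.0522), the S phase call without control replicate 3 (0.0819) or shCYTH4 replicate 1 (0.0689), and the cholesterol call without control replicate 3 (0.0788).

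The cytohesin and ARF list, 26 genes without CYTH4, was not called in MV4-11 (median 0.01, mean -0.05, camera direction down, adjusted p = 0.553), with 0 members called by edgeR over all genes and 0 over the list alone. CYTH1 was at 3.47 ± 0.435 FPKM in the controls and 3.94 ± 0.473 in the libraries labelled shCYTH4 (log2 0.10, SE 0.15), and ARF6 had a log2 change of 0.13 (SE 0.17). The 17 lists that were not called had adjusted p-values from 0.0996 to 0.995. Median, mean and test also differed in sign for the immediate early genes (median -0.07, mean 0.01, up), lysosome and autophagy genes (0.03, -0.01, down), the PI3K, AKT and mTOR components (0.04, 0.03, down) and nuclear-encoded oxidative phosphorylation genes (-0.0049, -8.6e-04, up).

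In total, edgeR called 139 of 12350 genes in MV4-11, 65 higher and 74 lower, with 96 at a log2 change of at least 1 and 1713 at an unadjusted p under 0.05. The balance of directions was not stable: higher and lower genes numbered 34 and 82 under quantile normalization, 10 and 36 at an adjusted p under 0.01, 22 and 53 without control replicate 2, and 34 and 76 without shCYTH4 replicate 1. The libraries of both arms separated for 139 of the calls and for 24.8% of all tested genes, where chance gives 10%. The count was 81 without control replicate 1, 75 without control replicate 2, 74 without shCYTH4 replicate 2, 88 without shCYTH4 replicate 3, and 398 without THP-1 shCYTH4 replicate 3, which enters through the shared estimate of the spread. Of the 23 named genes, between 6 and 11 lost their calls when 1 MV4-11 library was left out (10 without control replicate 1, 9 without 2 and 7 without 3; 6 without shCYTH4 replicate 1 and 11 each without 2 and 3). None did without THP-1 shCYTH4 replicate 3.

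In THP-1, where CYTH4 fell, the largest rises under the naming rule were those of CYP1B1, P4HA2 and WLS. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38076154), a cytochrome P450 induced by the aryl hydrocarbon receptor, rose from 0.538 ± 0.232 to 3.24 ± 0.761 FPKM (n = 3 each; log2 2.48, SE 0.31, adjusted p = 0.00266). P4HA2 (ENSG00000072682), a collagen prolyl hydroxylase subunit, rose from 0.452 ± 0.0533 to 2.24 ± 1.05 FPKM (log2 2.20, SE 0.32), and WLS, the Wnt secretion factor, from 0.552 ± 0.0365 to 2.11 ± 0.850 FPKM (log2 1.82, SE 0.32). HMOX1 (ENSG00000100292), haem oxygenase 1, rose from 1.95 ± 0.127 to 6.16 ± 3.16 FPKM (log2 1.55, SE 0.35, adjusted p = 0.0426); its shCYTH4 libraries held 8.32, 7.63 and 2.53 FPKM. The co-chaperone DNAJB2 rose by a log2 change of 1.49 (SE 0.21), the thiamine transporter SLC19A2 by 1.23 (SE 0.27), NPL, a sialic acid lyase, by 1.20 (SE 0.18) and TSPAN33 by 1.19 (SE 0.25).

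Under the same rule, the largest fall in THP-1 was that of H2BC21 (ENSG00000184678, chromosome 1, 149884459 to 149886682). It fell from 2.69 ± 0.727 to 0.738 ± 0.384 FPKM (log2 -1.98, SE 0.38, adjusted p = 0.0209) and, like H2AC20 (log2 -1.27, SE 0.30), codes for a core histone. Both levels are those of poly(A) RNA only. TNF (ENSG00000232810), the inflammatory cytokine, fell from 7.80 ± 2.52 to 3.54 ± 0.953 FPKM (log2 -1.25, SE 0.24, adjusted p = 0.0209). The lectin CD209 fell from 11.6 ± 1.91 to 5.09 ± 1.18 FPKM (log2 -1.30, SE 0.28), as did the cathepsin CTSW (log2 -1.50, SE 0.27) and MS4A4E (-1.33, SE 0.29). The readthrough transcript BCL2L2-PABPN1, which overlaps both of its parent genes, had a log2 change of -1.44 (SE 0.30), and ASH1L-AS1, antisense to ASH1L and overlapping MSTO1 on the same strand (mean 10.5 FPKM), one of -1.25 (SE 0.24). Adjusted p-values of the 8 falls ran from 0.0159 to 0.0474 and those of the 8 rises from 0.00266 to 0.0426.

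**Figure D3:**
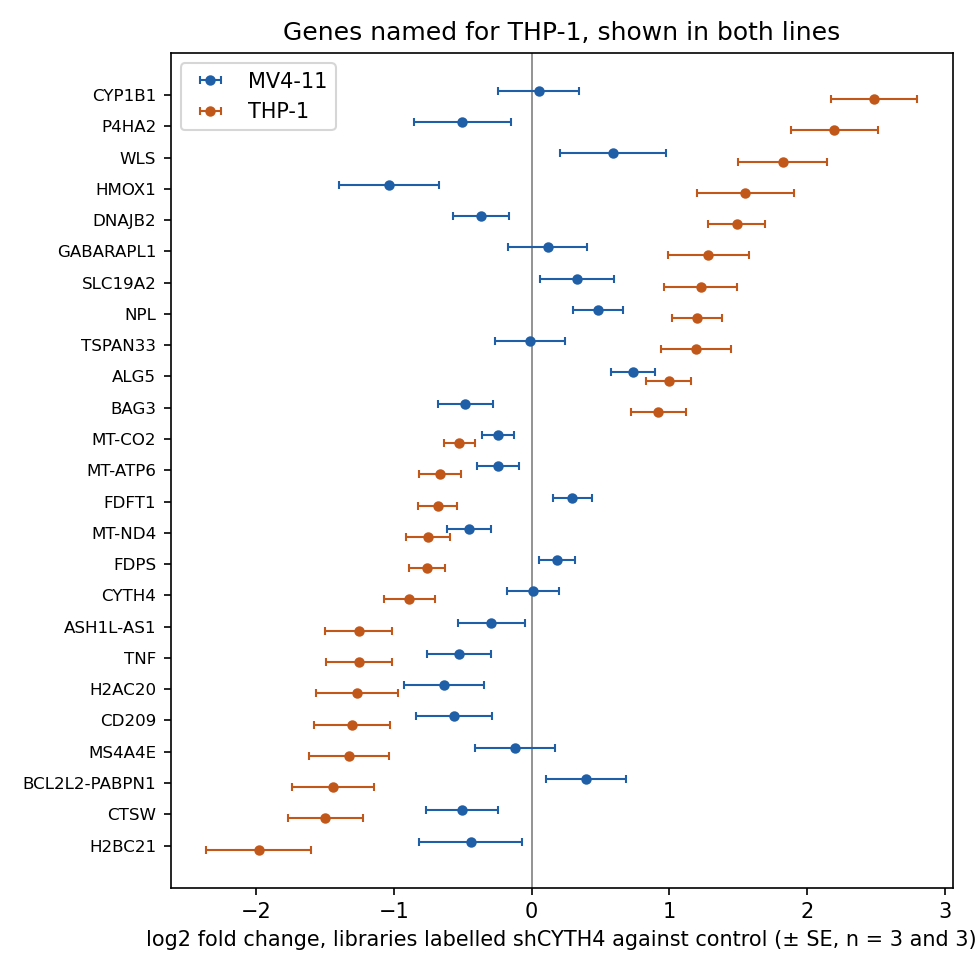
Log2 change of the named genes in THP-1, with bars for the standard error (3 libraries per arm). The values run from -1.98 for H2BC21 to 2.48 for CYP1B1, with CYTH4 at -0.89; MT-CO2 (-0.52) turns to 0.22 under quantile normalization.

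As groups, mitochondrially encoded mRNAs and cholesterol synthesis genes fell in THP-1 and heat shock genes rose, by the preset correlation only. The mitochondrial fall was mostly lost under quantile normalization (median -0.13). That scaling gives the highest levels of every library the same values. It can take away a joint fall of very abundant mRNAs such as these, so it cannot decide on this fall. All 13 mitochondrially encoded mRNAs were below 0 (median -0.54, camera adjusted p = 7.65e-10, but adjusted p = 0.366 with an estimated correlation), with 3 called lower and 10 adjusted over the list alone. MT-ND4 fell from 5265 ± 497 to 3394 ± 551 FPKM (log2 -0.75, SE 0.16), as did MT-ATP6 (log2 -0.67, SE 0.15) and MT-CO2 (-0.52, SE 0.12). Under quantile normalization all 3 lost their calls, with log2 changes of -0.13 for MT-ND4, -0.14 for MT-ATP6 and 0.22 for MT-CO2. The share of counts from mitochondrial genes was 7.11 ± 0.773% in the controls and 5.26 ± 0.758% with shCYTH4 (exact permutation p = 0.1, the smallest possible with 3 libraries against 3). In MV4-11 these shares were 7.30 ± 0.744% and 6.49 ± 0.703% (exact permutation p = 0.3). Cholesterol synthesis genes had a median of -0.37 with 16 of 19 below 0 (adjusted p = 1.45e-06, but adjusted p = 0.366 with an estimated correlation); 2 were called lower and 4 adjusted over the list alone. FDPS, farnesyl diphosphate synthase, fell from 89.4 ± 9.47 to 57.3 ± 5.12 FPKM (log2 -0.76, SE 0.13) as did FDFT1, squalene synthase (log2 -0.68, SE 0.14). All 13 heat shock genes were above 0 (median 0.58, adjusted p = 2.79e-07, but adjusted p = 0.386 with an estimated correlation), with 1 called and 8 adjusted over the list alone. The co-chaperone BAG3 rose from 11.1 ± 0.460 to 22.6 ± 7.29 FPKM (log2 0.92, SE 0.20). In a comparison chosen after the values were seen, the list medians of shCYTH4 replicates 1, 2 and 3 against the mean of the controls were 0.73, 0.87 and 0.05 for heat shock genes. They were -0.61, -0.51 and -0.09 for cholesterol synthesis genes and -0.65, -0.56 and -0.36 for mitochondrially encoded mRNAs, so the first pair of lists moved mainly in replicates 1 and 2.

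A further 8 lists passed in THP-1 with the preset correlation, and none of the 11 held with an estimated correlation (adjusted p = 0.366 to 0.471) or by fry (adjusted p = 0.109 to 0.170). Lower were ribosomal protein genes (median -0.26, 28 of 28 below 0), S phase and DNA replication genes (-0.25, 21 of 23), replication-dependent histones (-0.91, 6 of 7), glycolysis and hypoxia genes (-0.14, 18 of 20) and NF-kB and inflammatory genes (-0.08, 10 of 15), whose median turned to 0.03 with a pseudocount of 0.1 and to 0.0095 in limma on log2(FPKM + 1). The ribosomal median was -0.05 under quantile normalization, and in limma on log2(FPKM + 1) those of the S phase, histone and glycolysis lists were -0.14, -0.38 and -0.03. The histone values are those of poly(A) RNA only, so they need not hold for all transcripts of these genes. Higher were lysosome and autophagy genes (0.24, 18 of 22 above 0), interferon-stimulated genes (0.40, 17 of 23) and NRF2 targets and iron handling genes (0.29, 10 of 15). Called over all genes were H2BC21 for the histones, NDRG1 for glycolysis, TNF and IER3 for the inflammatory genes, GABARAPL1 for the lysosome, and HMOX1 and GCLM for NRF2. GABARAPL1, an autophagy adaptor, rose from 0.750 ± 0.162 to 1.98 ± 0.677 FPKM (log2 1.28, SE 0.29). Adjusted over the list alone, 0 to 5 members of these 8 lists passed; the ribosomal and S phase lists had 0 by edgeR on both counts. The NRF2 call was lost without control replicate 1 (adjusted p = 0.0819) or 2 (0.0762) or shCYTH4 replicate 1 (0.0509) or 2 (0.0655), and the histone call without control replicate 1 (0.151) or 2 (0.0947). The interferon call was lost without control replicate 2 (0.0647), the inflammatory call without shCYTH4 replicate 1 (0.0666) or 3 (0.160), the glycolysis call without control replicate 3 (0.0739) or shCYTH4 replicate 3 (0.225), and the S phase call without shCYTH4 replicate 3 (0.205).

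The cytohesin and ARF list was not called in THP-1 (median 0.13, mean -0.02, camera direction up, adjusted p = 0.700). ACAP1, a GTPase-activating protein for ARF6, was its 1 called member, falling from 0.371 ± 0.106 to 0.141 ± 0.0529 FPKM (log2 -1.50, SE 0.24, adjusted p = 0.0118); adjusted over the list alone, 3 members were higher and 3 lower. CYTH1 was at 5.38 ± 0.675 and 6.76 ± 0.391 FPKM (log2 0.22, SE 0.15, adjusted p = 0.535) and CYTH3 at 3.82 ± 0.393 and 6.15 ± 0.313 FPKM (log2 0.57, SE 0.19, adjusted p = 0.135). The 16 lists that were not called had adjusted p-values from 0.0731 to 0.825. Median, mean and test also differed in sign for the PI3K, AKT and mTOR components (median 0.02, mean -0.07, down) and the p53 targets (-0.0033, -0.03, up).

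**Figure D4:**
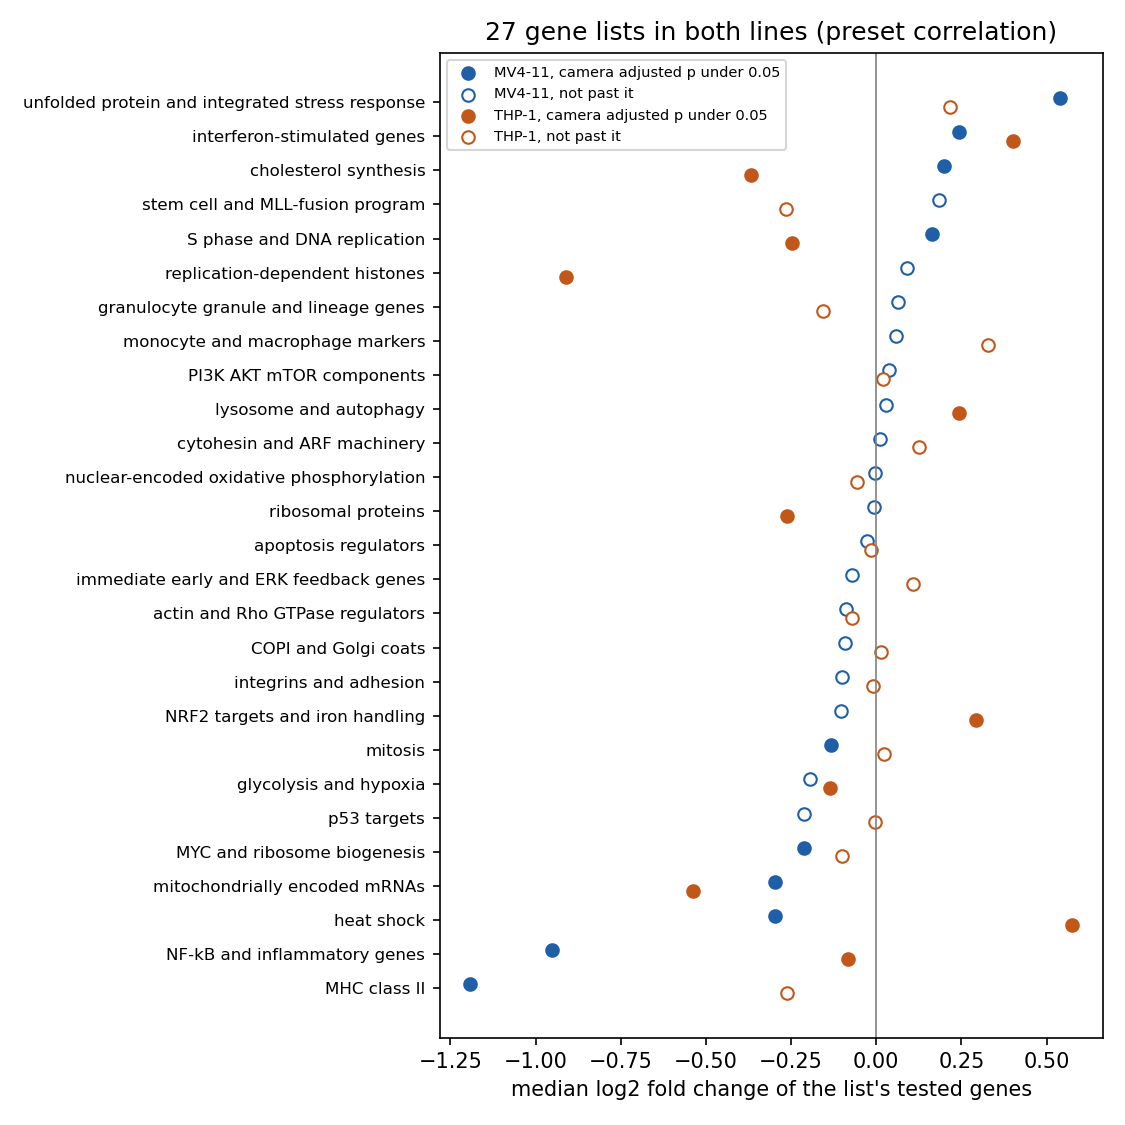
Median log2 change of the tested members of 27 gene lists in MV4-11 and THP-1, filled where camera at the preset correlation gave an adjusted p under 0.05 (10 lists in MV4-11, 11 in THP-1; with an estimated correlation 2 and 0). MHC class II (-1.19) and NF-kB and inflammatory genes (-0.95) are lowest in MV4-11; in THP-1 the latter (-0.08) turns to 0.03 with a pseudocount of 0.1.

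In total, edgeR called 204 genes in THP-1, 75 higher and 129 lower, with 81 at a log2 change of at least 1 and 1982 at an unadjusted p under 0.05. Higher genes made up 36.8% of the calls, but 62.6% with totals without mitochondrial genes, 64.7% with a pseudocount of 0.1 and 69.0% in limma on log2(FPKM + 1), and 12 of 50 without control replicate 3. The libraries of both arms separated for 203 of the calls and for 23.7% of all tested genes (chance 10%). THP-1 shCYTH4 replicate 3 stood apart from the other 2, at -2.73 on the first principal component where these lay at 33.0 and 37.4. Without it 835 genes were called, and all 24 named genes kept their calls. The count was 15 without shCYTH4 replicate 1, 29 without shCYTH4 replicate 2, 113 without control replicate 1, 25 without control replicate 2 and 50 without control replicate 3. Of the 24 named genes, these fits lost 20, 18, 7, 20 and 14, in that order.

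**Figure D5:**
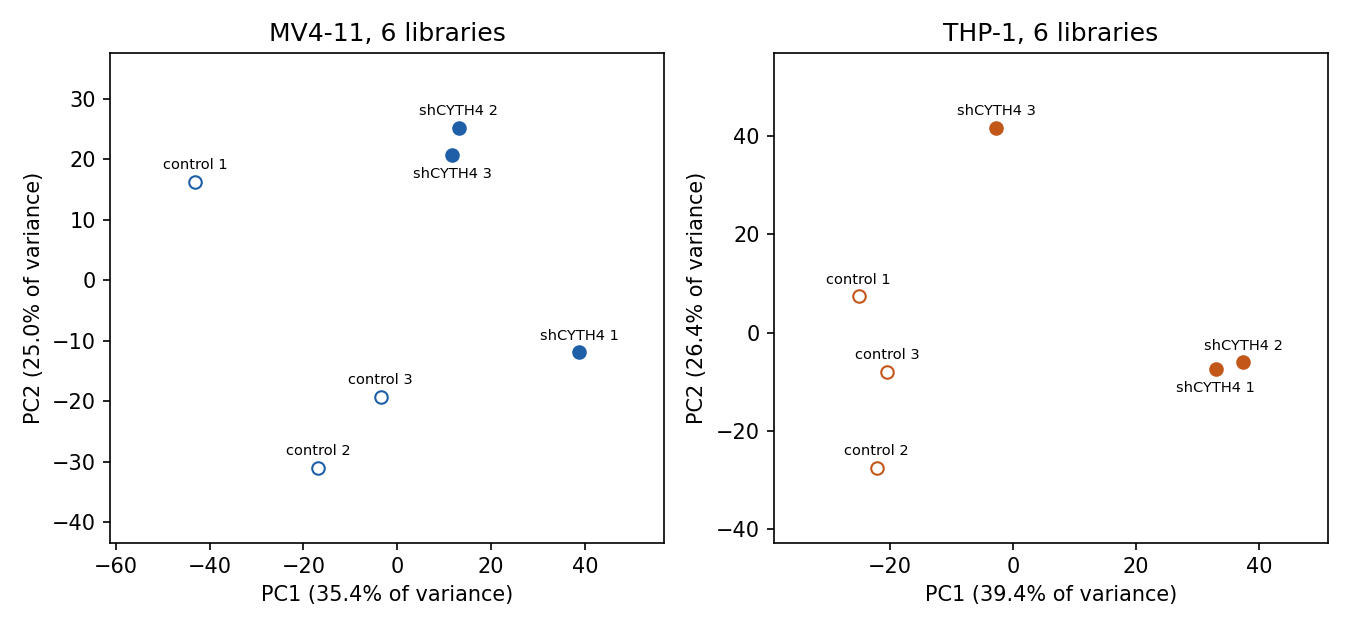
First and second principal components of the tested genes within each line, 6 libraries per panel (arbitrary units; first component 35.4% of the variance in MV4-11 and 39.4% in THP-1). THP-1 shCYTH4 replicate 3 lies at 41.7 on the second component, above the other 5 THP-1 libraries, which lie between -27.5 and 7.35.

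By edgeR, few genes were called in both lines, which are separate tests of the same hairpin label. Limma on log2(FPKM + 1), DESeq2 and array weights called more, as given with the alternatives below. ALG5, a glucosyltransferase of N-glycan assembly, rose in MV4-11 from 1.65 ± 0.272 to 2.89 ± 0.567 FPKM (log2 0.73, SE 0.16, adjusted p = 0.0356) and in THP-1 from 1.07 ± 0.159 to 2.29 ± 0.0196 FPKM (log2 0.99, SE 0.16, adjusted p = 0.0118). GPC4, a cell surface proteoglycan, was the other shared rise, and ALOX12, a lipoxygenase, and IER3 were the shared falls. GPC4 and ALOX12 are named because the counts are small, after their values were seen. Their log2 changes were 1.24 (SE 0.16) and 0.70 (SE 0.15) for GPC4 and -1.07 (SE 0.18) and -0.87 (SE 0.20) for ALOX12, in MV4-11 and THP-1. For IER3 they were -2.31 (SE 0.37) and -2.61 (SE 0.46). In THP-1 the levels were 0.330 ± 0.0857 and 0.0530 ± 0.0217 FPKM for IER3 and 0.883 ± 0.140 and 0.521 ± 0.0579 FPKM for ALOX12. Both shared falls thus stayed under 1 FPKM in THP-1. They drop out where a mean FPKM of at least 1 is asked of the higher group. The 2 shared rises stood against 0.395 for independent lists (Fisher's exact test, p = 0.0592) and the 2 shared falls against 0.773 (p = 0.181). LYZ and C6orf223 were called in opposite directions. Across the 12350 genes, which are not independent replicates, Pearson's r between the changes in the lines was -0.0143 and Spearman's rho 0.0382. The 4 shared calls became 0 without THP-1 control replicate 3 or shCYTH4 replicate 1, 1 each without MV4-11 control replicate 2, MV4-11 shCYTH4 replicate 2 or THP-1 control replicates 1 or 2, 2 each without MV4-11 shCYTH4 replicate 3 or THP-1 shCYTH4 replicate 2, and 16 without THP-1 shCYTH4 replicate 3.

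The test of the difference between the responses asked which changes differed between the lines. Measured CYTH4 was lower in THP-1 only, so effects of the line and of the knockdown cannot be told apart here. Of the genes named by the rule, C3 had the smallest adjusted p, with a log2 difference of -4.66 (SE 0.45, adjusted p = 3.19e-04): it fell in MV4-11 and was at 2.42 ± 0.210 and 3.31 ± 1.66 FPKM in THP-1 (log2 0.34). HIC1, a transcriptional repressor, differed by -3.03 (SE 0.49, adjusted p = 0.0125), from 2.80 ± 0.0671 to 1.12 ± 0.136 FPKM in MV4-11 and from 0.0473 ± 0.0170 to 0.163 ± 0.0839 in THP-1. CXCL10 (adjusted p = 0.0366) and CXCL14 (adjusted p = 0.0397) also had a lower response in MV4-11. Both have a group at 0, so no fold is given for the difference. In the other direction, FLRT1 differed by 3.05 (SE 0.56, adjusted p = 0.0303), KRT18, a keratin, by 4.80 (SE 0.54, adjusted p = 5.88e-04) and C6orf223 by 3.22 (SE 0.42, adjusted p = 0.00236). EMD, which codes for emerin of the nuclear envelope, differed by 3.10 (SE 0.55, adjusted p = 0.0162), but by -0.04 in limma on log2(FPKM + 1) and by -0.17 under quantile normalization. Its level was 30.5 ± 2.74 FPKM in the MV4-11 controls and, in the controls and with shCYTH4, 0.251 ± 0.0993 and 0.0232 ± 0.0217 in THP-1, under 3% of the level in MV4-11. KRT18 was at 0.525 ± 0.0620 and 0.0112 ± 0.00973 FPKM in THP-1 and was not called in limma on log2(FPKM + 1) or under quantile normalization; its adjusted p over all alternatives ran from 1.01e-05 to 0.962.

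Of 27 lists, 12 differed between the lines at the preset correlation, 6 in each direction, and none with an estimated correlation (adjusted p = 0.244 to 0.758) or by fry (adjusted p = 0.0520 to 0.460). Heat shock genes had the lower response in MV4-11 (median difference -0.89, 13 of 13 below 0, adjusted p = 2.19e-09, but adjusted p = 0.279 with an estimated correlation), as had MHC class II genes (-1.17, 6 of 7, adjusted p = 1.81e-06, but adjusted p = 0.244 with an estimated correlation). Cholesterol synthesis genes had the higher response in MV4-11 (0.67, 17 of 19 above 0, adjusted p = 1.71e-08, but adjusted p = 0.244 with an estimated correlation). Over all genes, BAG3 was the 1 heat shock gene called, HLA-DRB1 was among 2 MHC class II genes and FDPS and FDFT1 were the cholesterol genes; adjusted over the list alone there were 8, 4 and 8. Median, mean and test differed in sign for monocyte markers, glycolysis and hypoxia genes, immediate early genes and the PI3K, AKT and mTOR components, none of them called.

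EdgeR called 107 genes for the difference, 51 with the higher response in MV4-11 and 56 with the lower, with 100 at a log2 difference of at least 1 and 1752 at an unadjusted p under 0.05. The count was 60 without MV4-11 control replicate 2, 47 without MV4-11 shCYTH4 replicate 2, 55 without MV4-11 shCYTH4 replicate 3, 53, 40 and 46 without THP-1 control replicates 1, 2 and 3, 32 and 46 without THP-1 shCYTH4 replicates 1 and 2, and 913 without THP-1 shCYTH4 replicate 3. Of the 8 named genes, C3 and C6orf223 kept their calls under every alternative. Leaving out 1 library ended the calls of 4 without THP-1 shCYTH4 replicate 1, of 3 each without MV4-11 control replicate 3, MV4-11 shCYTH4 replicates 2 or 3 or any THP-1 control, of 2 without MV4-11 shCYTH4 replicate 1, and of 1 each without MV4-11 control replicates 1 or 2 or THP-1 shCYTH4 replicate 2.

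The control libraries gave the baseline of the lines. CDKN2A, the cell cycle inhibitor locus, was at 20.5 ± 0.253 FPKM in MV4-11 and 0.0808 ± 0.0354 in THP-1 (n = 3 each; log2 7.88, SE 0.54, adjusted p = 1.7e-07), and FAM50B at 4.75 ± 0.263 and 0.0143 ± 0.0130 (log2 8.25, SE 0.42). CXCL14, EDA2R and PRAC2 were at 0 in all 3 THP-1 controls and at least 110-fold, 84.8-fold and 11.2-fold higher in MV4-11 at the same floor. HOXA7, a homeobox gene, was at 0 in all 3 MV4-11 controls and at least 41.3-fold higher in THP-1, as were PLBD1 (at least 36.0-fold), LINC01436 (at least 30.0-fold) and ZNF385D-AS1 (at least 14.9-fold). ANOS1 was at 0.00226 ± 0.00392 FPKM in MV4-11 and 2.03 ± 0.698 in THP-1 (log2 -9.55, SE 0.70). Interferon-stimulated genes were lower in MV4-11, with 23 of 23 below 0, 22 called and 23 adjusted over the list alone (median -2.50, adjusted p = 5.5e-14, and adjusted p = 0.00557 with an estimated correlation).

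A further 5 lists differed between the control libraries at the preset correlation and not with an estimated one. Higher in MV4-11 were p53 targets (median 1.14, 16 of 19 above 0; adjusted p = 0.206 with an estimated correlation), NF-kB and inflammatory genes (1.11, 15 of 15; adjusted p = 0.352 with an estimated correlation), MYC and ribosome biogenesis genes (0.68, 20 of 20; adjusted p = 0.752 with an estimated correlation) and MHC class II genes (1.32, 6 of 7; adjusted p = 0.840 with an estimated correlation). Monocyte and macrophage markers were lower (-1.81, 9 of 11 below 0; adjusted p = 0.224 with an estimated correlation). Fry called 14 lists. EdgeR called 6347 genes, 3044 higher and 3303 lower in MV4-11, with 3059 at a log2 change of at least 1. The libraries of the lines separated for 60.6% of all tested genes (chance 10%).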

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

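The tests of exchanged arms, a small reduction, the wrong line, library size, single libraries, scaling and a control held out with replicate 3 were chosen only after the results were seen; those of a wrong label, a mixture, B cells and other splits were set earlier.

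CYTH4 was not lower in the MV4-11 libraries labelled shCYTH4. An exchange of the arms, with a knockdown of the size seen in THP-1, would need a log2 change of at least 0.49, and the upper bound of the MV4-11 interval was 0.40, which argues against it. Libraries of the wrong cell line are argued against as well, since 12 of 12 libraries were nearer to their own line (lowest correlation 0.962 within and highest 0.825 across lines). A reduction too small to be seen stays open, as the interval reaches down to -0.39 on the log2 scale, 76.5% of the control level. A change in CYTH4 protein without one in its mRNA, or an effect of the hairpin on other targets, was not tested.

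THP-1 shCYTH4 replicate 3 stood apart from replicates 1 and 2. A mixture of knockdown and control RNA is argued against as the whole cause by the bound set earlier, at least 2 times the median of the other libraries: of 6161 genes, 55 lay outside the range of the other 5 libraries by 1.5 times, against a median of 9 for those libraries, but 33 for the highest, control replicate 3; a library size of 73.0 M counts was within the range of the others. A control library with the wrong label stays open: over genes called without it, replicate 3 sat at 0.280 between the controls (0) and the other knockdown libraries (1), where replicates 1 and 2 sat at 1.10 and 0.890 when held out. The bound set earlier against it, at least 0.25 with CYTH4 below every control (15.7 FPKM, a value already seen), was met but not used, by a requirement added after the 0.280 was seen, because control replicate 1 held out sat at 0.314. With control replicate 1, 2 or 3 held out beside it, replicate 3 was higher each time (positions 0.383, 0.230 and 0.305 against 0.1001, 0.195 and 0.146, and 93, 64 and 66 genes beyond the other controls by 1.5 times on the knockdown side against 5, 20 and 37), which leans against a wrong label but met neither margin set before these runs, more than the spread of the control positions and at least 2 times the genes of the control.

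NF-kB, inflammatory and MHC class II genes were lower in the MV4-11 libraries labelled shCYTH4. That a single library decides the direction is argued against, since with 1 library left out all members stayed below 0 and the list median nearest 0 was -0.78; this replaced a test on adjusted p-values at the preset correlation, and with an estimated one both calls were lost without any 1 of the libraries labelled shCYTH4 (adjusted p = 0.0548 to 0.0760). The choice of scaling is argued against too: under 6 other scalings and pseudocounts all members of both lists stayed below 0, with list medians nearest 0 of -0.77 each, a test that replaced one on the called members alone. B cells among the control cells stay open: the 1 B cell marker of 8 found with at least 1 FPKM in the controls, FCER2, had a log2 ratio of -0.0639 and cannot speak for the type, while IGKC, chosen after its values were seen, fell from 32.9 ± 3.21 to 8.13 ± 1.09 FPKM (log2 -2.09, adjusted p = 0.0287). With no measured fall of CYTH4 there, a response to CYTH4 loss may be 1 biological hypothesis among others, and these libraries cannot test it.

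Splits of the libraries other than the real one were run for each count. In MV4-11, 1 of the 10 splits, the real one, gave as many as 139 genes (highest other 11), and 1 of 10 gave as many as 10 lists (highest other 7). In THP-1, 1 of 10 gave as many as 204 genes (highest other 14) and 2 of 10 gave as many as 11 lists (highest other 14). For the control libraries, 1 of 10 gave as many as 6347 genes (highest other 1). With 10 splits, all of these are too few for a share under 0.05. For the difference between the lines, 2 of 100 splits gave as many as 107 genes, the real split and another that called 250. The latter regrouped no library: it kept the arms in MV4-11 and exchanged them in THP-1, so it tests the sum of the responses. Among splits that regrouped libraries the highest count was 29, but regrouping the libraries of a line also removes the difference between its arms. Low counts were therefore likely, and these splits cannot tell whether the responses differ by more than chance. For the 4 shared calls, 1 of 100 gave as many (highest other 2), but only 3 of 100 splits called at least 4 genes in each line, so this count excludes nothing. For the lists that differed between the lines, 9 of 100 gave as many as 12 (highest other 16), so chance is not excluded. Other splits called a median of 5 to 7 lists, so camera at the preset correlation calls lists readily in these libraries.

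The responses of the lines differed, by the interaction test, for 107 genes, for 20 of 51 named genes and, at the preset correlation, for 12 of 27 lists. As measured CYTH4 was lower in THP-1 only, these differences need not be ones between lines in the response to CYTH4 loss. Of the 20, 8 were named because this test called them and the others for their change in 1 line, so that share is partly set by the choice of genes. None of the 12 lists held with an estimated correlation (adjusted p = 0.244 to 0.758), and 9 of 100 splits gave as many. The response was lower in MV4-11 for C3 (log2 difference -4.66, SE 0.45), HIC1 (-3.03, SE 0.49), P4HA2 (-2.70, SE 0.47), HMOX1 (-2.59, SE 0.50), IL4I1 (-2.58, SE 0.41), CYP1B1 (-2.43, SE 0.42), RTL8C (-2.06, SE 0.32), CHST2 (-1.97, SE 0.28), DNAJB2 (-1.85, SE 0.29), BAG3 (-1.40, SE 0.28), RELB (-1.24, SE 0.24) and HLA-DRB1 (-1.20, SE 0.25), with adjusted p-values from 3.19e-04 to 0.0378. The response was also lower for CXCL10 (-10.14) and CXCL14 (-8.72), whose fitted values rest on groups at 0 and bound nothing. It was higher in MV4-11 for FDPS (0.94, SE 0.19), FDFT1 (0.98, SE 0.20), FLRT1 (3.05, SE 0.56), EMD (3.10, SE 0.55, but -0.0389 in limma on log2(FPKM + 1) and -0.17 under quantile normalization), C6orf223 (3.22, SE 0.42) and KRT18 (4.80, SE 0.54), with adjusted p-values from 5.88e-04 to 0.0331.

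Lists with a lower response in MV4-11 were heat shock (median difference -0.89), MHC class II (-1.17), NF-kB and inflammatory (-0.49), NRF2 and iron handling (-0.48), lysosome and autophagy (-0.25) and mitosis genes (-0.20). Those with a higher response were replication-dependent histones (1.08), cholesterol synthesis (0.67), the unfolded protein and integrated stress response (0.49), the stem cell and MLL-fusion program (0.44), S phase and DNA replication (0.34) and ribosomal proteins (0.26). The values nearest 0 were 0.50 for histones, 0.13 for ribosomal proteins, 0.25 for the stress response and -0.13 for mitosis under quantile normalization, and 0.28 for the stem cell list in limma on log2(FPKM + 1). Calls were lost for mitosis without MV4-11 control replicates 2 (adjusted p = 0.0825) or 3 (0.123), MV4-11 shCYTH4 replicates 2 (0.107) or 3 (0.0814), THP-1 control replicate 3 (0.117) or THP-1 shCYTH4 replicate 3 (0.568). For histones this happened without MV4-11 control replicate 2 (0.0825), MV4-11 shCYTH4 replicates 2 (0.0509) or 3 (0.0568), THP-1 control replicates 1 (0.183) or 2 (0.242), or THP-1 shCYTH4 replicates 1 (0.0561) or 3 (0.0815). The stress response call was lost without MV4-11 control replicate 2 (0.0825) or shCYTH4 replicate 1 (0.179), the ribosomal call without THP-1 control replicate 2 (0.0806) or shCYTH4 replicate 3 (0.124), and the lysosome and stem cell calls without MV4-11 control replicate 1 (0.0697 each).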

How the results depend on the processing

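Limma on log2(FPKM + 1) was the test planned for a table without raw counts. It was run as an alternative to edgeR only after the results were seen. The divided counts, the filter on the higher group and the test without genes under 3% of the other line's level were chosen then as well. So were the MV4-11 and control fits without THP-1 shCYTH4 replicate 3. Of the named genes, 12 of 23 in MV4-11, 3 of 24 in THP-1 (CYP1B1, P4HA2 and DNAJB2), 2 of 8 for the difference and 10 of 10 for the control libraries kept direction and call under every alternative run. For CYTH4, the log2 change in MV4-11 stayed between -0.09 and 0.26 and was never called; in THP-1 it was lower under every alternative. In simulated data, where no library stood apart, the test recovered 67.2% of 2-fold and 20.9% of 1.5-fold changes in MV4-11. In such data, depth and 3 libraries per group leave smaller changes mostly uncalled. Under no alternative was the median log2 change of all tested genes more than 0.1 from 0 (largest 0.0976, with a pseudocount of 0.1). DESeq2 also made more false calls than edgeR in simulated data.

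The counts outside 1.5 times the value reported were as follows, and where no cause is given the cause was not tested. At an adjusted p under 0.01, by construction fewer, 46 genes were called in MV4-11, 15 in THP-1, 14 for the difference and 0 in both lines by edgeR. With a mean FPKM of at least 5, where fewer genes are tested, these were 65, 133, 25 and 2, and 3035 for the control libraries. Array weights gave 2311, 2999, 3080 and 253, and DESeq2 451, 611, 441 and 31. Limma on log2(FPKM + 1) gave 477 in THP-1, 162 for the difference and 9 in both lines; quantile normalization gave 482 and 174 for the first of these pair. Totals without mitochondrial genes gave 131 in THP-1, where higher genes went from 36.8% to 62.6% of the calls. The 6 libraries of 1 line alone, with fewer samples, gave 78 in THP-1 and 0 in both lines, where edgeR on all 12 libraries gave 4. A mean FPKM of at least 1 in the higher group gave 2 in both lines. In MV4-11 higher genes went from 46.8% to 29.3% of the calls under quantile normalization.

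With a replicate block, 23 genes were called in THP-1, 47 for the difference and 0 in both lines, and CYTH4 in THP-1 changed by -0.86 (adjusted p = 0.131; over its alternatives 3.7e-04 to 0.147). Replicate numbers did not pair the libraries: correlations of their deviations ran from -0.214 to 0.0945, and no library was closest to the one of its own number, so the block removes degrees of freedom without a shared source.

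Leaving out 1 library, counts ran from 74 to 398 in MV4-11, 15 to 835 in THP-1, 32 to 913 for the difference, 5398 to 6709 for the control libraries and 0 to 16 for both lines; the highest was in each case the fit without THP-1 shCYTH4 replicate 3. CYTH4 ran from -1.03 to -0.67 in THP-1 and from -0.09 to 0.16 in MV4-11. Lists called ran from 8 to 10, 9 to 12 and 10 to 13 for MV4-11, THP-1 and the difference. With an estimated correlation 2, 0 and 0 lists were called by camera, where 10, 11 and 12 were called at the preset one. Among the named genes, direction reversed in 3 cases: MT-CO2 in THP-1 under quantile normalization (0.22), and EMD for the difference in limma on log2(FPKM + 1) (-0.0389) and under quantile normalization (-0.17). The median of the NF-kB and inflammatory list in THP-1 also turned, to 0.03 with a pseudocount of 0.1 and to 0.0095 in limma on log2(FPKM + 1). The causes were not tested.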

Other observations

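The genes and terms of this part, and its test of a stress response, were chosen only after the results were seen.

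Gene ontology terms were tested only among the 9129 tested genes with an entry in the file. These held 47 of the 74 falls in MV4-11 and 88 of the 129 falls in THP-1. Within them, the falls in MV4-11 were enriched for cytokine activity (4 of 31 genes against 0.160 expected, Fisher's exact test, one-sided, adjusted p = 0.0154 over 1756 terms), with CD70, GDF11 and the named genes CXCL14 and EBI3. The called chemokines CXCL10 and CCL2 were not counted in that term. CD70, a ligand of the TNF family, fell from 35.5 ± 3.68 to 14.3 ± 0.456 FPKM (n = 3 each; log2 -1.39, SE 0.16, adjusted p = 3.34e-04), and its response differed from that in THP-1 (log2 difference -1.28, adjusted p = 0.0162). Protease binding (4 of 30 genes, adjusted p = 0.0154) and the extracellular space (9 of 346, adjusted p = 0.0324) were the other terms. In THP-1, falls were enriched for structural constituents of chromatin (5 of 37 against 0.357 expected, adjusted p = 0.0223), namely H2AC18, H2AC20, H2AX, H2BC21 and H3-7, for the nucleosome (5 of 42, the same 5 genes, adjusted p = 0.0279) and for the defence response to bacteria (5 of 29, adjusted p = 0.0129: CFP, GSDMD, H2BC21, MPEG1 and SPON2). The histone levels are again those of poly(A) RNA only. H2AX, a histone of the DNA damage response, fell from 98.8 ± 10.9 to 56.8 ± 6.14 FPKM (log2 -0.92, SE 0.15, adjusted p = 0.0119). No term passed for the rises of either line.

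LYZ, the most abundant monocyte marker, fell in MV4-11 from 1707 ± 129 to 1119 ± 25.5 FPKM (log2 -0.68, SE 0.12, adjusted p = 0.0107) and rose in THP-1 from 331 ± 53.1 to 705 ± 49.6 FPKM (log2 0.98, SE 0.12, adjusted p = 0.00188), a log2 difference of -1.67 (adjusted p = 3.19e-04). LYZ does not stand for the monocyte and macrophage markers, a list called in neither line. In MV4-11, 6 of its members were above 0 and 5 below (camera adjusted p = 0.664). In THP-1, the member FCGR1A was called lower by edgeR (log2 -0.71, adjusted p = 0.0331). SLFN11, a factor that blocks stressed replication forks, rose in MV4-11 from 0.172 ± 0.0234 to 0.914 ± 0.101 FPKM (log2 2.33, SE 0.17, adjusted p = 5.12e-06), with a log2 difference of 2.43 from THP-1 (adjusted p = 1.49e-04), where it did not change (log2 -0.10, SE 0.15, adjusted p = 0.817).

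Genes of the integrated stress response were among those that set THP-1 shCYTH4 replicate 3 apart. CHAC1, a target of ATF4, was at 7.95 to 8.79 FPKM in the THP-1 controls, at 1.10 and 0.478 in shCYTH4 replicates 1 and 2 and at 17.3 in replicate 3. DDIT4, an inhibitor of mTORC1, was at 31.1 to 35.8 FPKM in the controls and at 10.3, 11.6 and 39.4 with shCYTH4, and TRIB3 at 23.5 to 36.3 and at 20.9, 16.6 and 62.0. Without replicate 3, CHAC1 fell in THP-1 by 3.47 (adjusted p = 4.03e-05) and DDIT4 by 1.70 (adjusted p = 1.14e-04) on the log2 scale. In the same fit HSPA5 (0.65, adjusted p = 0.0107), CALR (0.49, 0.0312) and PDIA4 (0.44, 0.0466) rose, and the list had 3 members called higher and 6 lower, 11 above 0 and 10 below (adjusted p = 0.380 with an estimated correlation). In MV4-11, CHAC1 was at 2.31 ± 0.654 and 11.4 ± 0.577 FPKM (adjusted p = 0.409 over all libraries and 2.05e-04 without THP-1 shCYTH4 replicate 3) and ASNS, asparagine synthetase, at 6.80 ± 2.35 and 35.4 ± 4.07 (adjusted p = 0.112 and 0.00180). The stress response list in MV4-11 without that library had 10 members called higher and 2 lower (adjusted p = 0.0212 with an estimated correlation), but adjusted p = 0.223 over all libraries and 0.155 in the MV4-11 libraries alone, with 8 higher and 1 lower.

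A candidate explanation for the place of that library is a stress response in its culture, such as a lack of amino acids. The median log2 ratio of the 21 list members to replicates 1 and 2 was 0.72, with 15 members higher, at percentile 100 of 10000 random lists. The test is not specific, since 13 of the 27 lists lay outside the middle 95% of random lists, 8 above and 5 below, and it does not tell a stressed culture from replicates 1 and 2 being the ones that differ.

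Each line held traces of transcripts high in the other. In THP-1, the median of 20 such genes stood at 1.38 ± 0.196% of their MV4-11 level in the controls and 0.642 ± 0.212% with shCYTH4 (exact permutation p = 0.1, the smallest possible), and in MV4-11, that of 38 genes stood at 0.819 ± 0.267% and 0.804 ± 0.138% of their THP-1 level (exact permutation p = 1). Summed over the 20 genes, the THP-1 share differed less, with 1.36% to 1.58% in the controls and 1.04% to 1.32% with shCYTH4. Of the calls, 2 of 139 in MV4-11 and 8 of 204 in THP-1 were genes under 3% of the level in the other line, as were 265 and 73 of the 12350 genes tested.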
